A study of Homo sapiens with 12 samples.

How the data were processed

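RNA was measured in 12 libraries of human melanoma cells, 3 for each combination of line (WM852, WM115) and caspase-reporter state (positive, negative). Per the labels' protocols, libraries were made from 600 ng of total RNA with a stranded, poly(A)-selecting kit and sequenced in pairs of 75 bp reads on a NextSeq500. Per the submitters' processing notes, the authors used the hg38 build, MultiQC 1.7 and edgeR 3.26.7. The aligner, the gene annotation and whether counting used strand are not given in the sources used here. The deposited table held RPKM values (reads scaled to gene length and to the size of the library) made by the authors, one row per Entrez gene for 28010 genes and one column per library. Each column was assigned to its library by its name, and no column of another sample was present (0). Of the Entrez identifiers, 27744 were found in a RefSeq gene table of GRCh38.p14, which gave the coordinates.

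RPKM values fix the relative level of genes within a library and remove depth from the values. Depth was recovered from the steps between low values, since a gene's RPKM is a whole multiple of what 1 read is worth. All kept genes (100%) gave whole reads in every library within a relative deviation of 1.1e-06. This gave 16291586 reads in the shallowest library and 22923873 in the deepest, a ratio of 1.41, and a median of 608 reads per kept gene and library. The per-library total behind the RPKM differed from the recovered one by up to 1.29%. The reads were used for depth, replicate checks, the simulation, the tests of read ratios, read sums of some genes and an alternative test, and not for the main tests. Of all genes, 5809 were at 0 in every library. No transcript of the mitochondrial genome was analysed here, so that list of 13 genes gave no result.

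Values were used as deposited with no further scaling. Genes with at least 1 RPKM in at least 3 of the 12 libraries were kept, whatever the group, which left 12376. The test was limma 3.58.1 (in R 4.3.3) on log2(RPKM + 0.5), with 1 model of 4 group means over all 12 libraries, an intensity-dependent prior (trend) and no robust option, giving 8 residual and 3.40 prior degrees of freedom. It was two-sided, with Benjamini-Hochberg adjustment over all kept genes within each comparison, a threshold of 0.05 and no fold minimum. The comparisons were positive minus negative cells in WM852, the same in WM115, the difference of these effects between lines, and WM852 minus WM115 in negative cells. Genes past the threshold in both lines were compared per direction with Fisher's exact test.

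Gene lists (33, from textbook knowledge) were written before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes. The lists of AP-1 subunits, of feedback regulators of MAPK and JNK, and of actin and motility genes were written knowing the topic of the study. Lists with at least 3 kept genes (30) were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the 30 lists of each comparison. The blood cell and endothelial lists kept fewer than 3 genes.

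Genes were named by a rule. BID came first, then the 10 highest and 10 lowest fold changes per comparison among genes that passed, whose groups did not overlap, and whose higher group had a mean of at least 2 RPKM. Genes with a clone-based, antisense, pseudogene or uncharacterised name were left out. The rule added 10 shared genes per direction, the 5 highest and 5 lowest differences between lines, and up to 4 members with the smallest p in each list. COL1A2, COL3A1, DCN, TNFRSF10D and AGTR1 fall outside it and were chosen after values were seen. Some genes are not reported here, and the tests of read ratios for genes near 0 in WM115 or far higher in positive WM852 cells were run without them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

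Replicates were compared before averaging. A chi-square test of recovered reads over genes gave 1.31 to 4.13 per degree of freedom for pairs within a group, so no pair differed by less than sampling noise. The largest values were those of WM115 negative library 2 against libraries 1 and 3 (4.13 and 3.22). The procedure was tested on simulated reads for 12376 genes, with 50 genes changed at each fold. For the WM852 comparison it recovered 58% of genes changed 1.2-fold, 90% at 1.5-fold and 98% at 2-fold, and 3.37% of its calls were false. For the WM115 comparison it recovered 72%, 86% and 94%, with 3.85% false calls. A comparison simulated without change gave 0 calls. All simulated genes had 1 dispersion, 0.000202, and no library deviated as WM115 negative library 2 did. These rates may therefore be better than those in the real libraries.

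The alternatives were pseudocounts of 0.1 and 1, no filter on low values or a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, a robust prior, a 2-fold minimum, a fit of only the libraries compared, the replicate number as a block, an estimated correlation for lists, and leaving out each library in turn. One alternative, limma voom on the recovered reads, was chosen after seeing the data.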

Results

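Gene expression was measured by RNA sequencing in WM852 and WM115, 2 human melanoma cell lines of different metastatic potential per the labels. The cells carried a doxycycline-inducible truncated BID, the active form of a pro-apoptotic protein that permeabilises mitochondria through BAX. They also carried VC3AI, a caspase reporter in which fragments of a fluorescent protein come together once caspases act on it. Cells negative for DAPI and for annexin V, which stain dead and dying cells, were sorted into reporter-positive and reporter-negative populations. Each of the 4 groups (line by reporter state) held 3 libraries. The question was how melanoma cells that had activated caspases and were still alive differed from reporter-negative cells of the same line. Doxycycline ranged from 10 ng/mL to 1 µg/mL, and the dose behind each library is not given in the sources used here. The deposited values were RPKM per gene for 28010 genes. They fell on steps that correspond to whole reads, which gave 16291586 to 22923873 reads per library, with a median of 608 reads per tested gene and library. The smallest exact permutation p for 3 libraries against 3 is 0.1, so single genes were tested with limma, which pools information on the spread across genes. All p-values measure only the spread between these libraries, since nothing says that they came from separate cultures. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. Errors of fold changes are standard errors from the model and errors of levels are standard deviations over 3 libraries.

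BID (Entrez gene 637, chromosome 22, 17734138 to 17774665 in GRCh38.p14) was measured first, because truncated BID was the induced gene. In WM852 its level was 11.1 ± 0.447 RPKM (SD, n = 3) in positive cells and 11.7 ± 0.158 RPKM in negative cells. In WM115 it was 12.9 ± 0.225 RPKM in positive cells and 13.2 ± 0.253 RPKM in negative cells. The log2 fold change was -0.07 ± 0.03 in WM852 (adjusted p = 0.292) and -0.03 ± 0.03 in WM115 (adjusted p = 0.694), so neither difference passed the test. One value per gene does not separate reads of the induced construct from reads of the cell's own BID.

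Several genes were far higher in reporter-positive than in reporter-negative WM852 cells. FSTL1, a secreted glycoprotein (Entrez gene 11167, chromosome 3, 120392293 to 120450992), rose from 0.344 ± 0.0801 to 8.26 ± 0.347 RPKM (SD, n = 3), a log2 fold change of 3.38 ± 0.09 (adjusted p = 8.7e-10), and PXDN, a peroxidase that cross-links collagen IV, rose by 2.94 ± 0.09 (adjusted p = 4.2e-09). The actin-binding genes FLNC and CNN1 rose by 2.51 ± 0.10 and 2.40 ± 0.12. LOX, the enzyme that cross-links collagen, rose by 2.28 ± 0.10, and COL1A1, a chain of type I collagen, by 2.22 ± 0.09. BASP1, a membrane-bound signalling protein, rose by 2.37 ± 0.12, UCHL1, a ubiquitin hydrolase, by 2.31 ± 0.13, and RAC2, a small GTPase, by 2.18 ± 0.12. These 9 genes were among the 10 that the naming rule took for the largest increases, and in each of them all 3 positive libraries lay above all 3 negative ones.

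Fewer genes fell in positive WM852 cells, and by less. SOD3, the extracellular superoxide dismutase (Entrez gene 6649, chromosome 4, 24795573 to 24800842), fell from 4.70 ± 0.420 to 1.52 ± 0.302 RPKM, a log2 fold change of -1.37 ± 0.10 (adjusted p = 9.0e-06). SERPINA3, the protease inhibitor alpha-1-antichymotrypsin, changed by -1.04 ± 0.10 (adjusted p = 8.2e-05) and TXNIP, the thioredoxin-interacting protein, by -0.78 ± 0.08. EDNRB, an endothelin receptor of the melanocyte lineage, changed by -0.62 ± 0.07. Smaller decreases were measured for S100A1 (-0.56 ± 0.11), FGF13 (-0.54 ± 0.09), IGFLR1 (-0.46 ± 0.08) and CHRDL1 (-0.46 ± 0.06). MIRLET7I and MIR4720 passed as well, at -2.04 ± 0.48 and -1.53 ± 0.32, but on 4 against 20 and 6 against 21 recovered reads summed over the 3 libraries of each group. In all, 550 of 12376 genes passed in WM852, 391 higher and 159 lower in positive cells, and 46 of them changed at least 2-fold, 42 higher and 4 lower. With each WM852 library left out in turn, 233 to 280 genes were higher and 65 to 103 lower. The count of 550 was 301, 321, 349, 358 and 318 without positive library 1, positive library 2, negative library 1, negative library 2 and negative library 3, respectively, 315 when only genes with a mean of at least 5 RPKM were tested, and 903 with limma voom on the recovered reads. With the 6 WM852 libraries left out singly, the call was lost without 5 of them for MIRLET7I, 3 for MIR4720 and 4 for S100A1, with adjusted p up to 0.121, 0.0735 and 0.0705.

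Among the gene lists fixed before the data were examined, markers of the undifferentiated, invasive melanoma state rose in positive WM852 cells. Of 16 members tested, 6 rose, none fell and 10 did not pass, and 8 rose when adjusted over the list alone. F2RL1, a protease-activated receptor, rose by 1.35 ± 0.07, SOX9, a neural crest transcription factor, by 1.61 ± 0.11, and NGFR, the nerve growth factor receptor, by 0.42 ± 0.05 (camera adjusted p = 4.2e-10 for the list, and 0.012 with an estimated correlation). Proteases of the matrix and their inhibitors rose with 10 of 25 members higher, 1 lower and 14 not past the test, and 12 higher and 4 lower when adjusted over the list alone (adjusted p = 3.7e-07, and 0.012 with an estimated correlation). They included PLAU, the urokinase, at 1.66 ± 0.12, the collagenase MMP1 at 0.38 ± 0.05 and the inhibitor TIMP2 at 0.34 ± 0.04. With each WM852 library left out in turn, 6 to 10 of these members rose and 0 or 1 fell. Of 14 interferon-stimulated genes, 5 rose and 9 did not pass, and 6 rose when adjusted over the list alone. The RNA sensor DDX58 rose by 0.88 ± 0.08, the antiviral genes IFI44 and BST2 by 1.19 ± 0.12 and 1.30 ± 0.14 (adjusted p = 1.1e-05 for the list, and 0.0169 with an estimated correlation). The list missed the threshold when only genes with a mean of at least 5 RPKM were tested, the highest of its adjusted p-values over the alternatives, which ran from 9.3e-10 to 0.0595.

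Mesenchymal genes and integrins also rose as lists in WM852. Of 14 mesenchymal markers and regulators, 4 rose and 10 did not pass, and 5 rose when adjusted over the list alone (adjusted p = 0.00026, and 0.0318 with an estimated correlation). The list median was 0.05 and its mean 0.26, so few members carried most of the mean. Next to LOX, the fibronectin gene FN1 rose by 0.23 ± 0.03 from a high level, 174 ± 1.43 RPKM in negative cells. Of 14 integrins, 4 rose, 1 fell and 9 did not pass, and 5 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00278, and 0.0336 with an estimated correlation). ITGA5 rose by 0.26 ± 0.04, ITGAV by 0.28 ± 0.05 and ITGB4 by 0.45 ± 0.08, whereas ITGA9 changed by -0.39 ± 0.07. Of 4 fibroblast markers that could be tested, COL1A1 and FAP rose and 2 did not pass, and 3 rose when adjusted over the list alone (adjusted p = 3.4e-06, and 0.012 with an estimated correlation). FAP, a serine protease of activated fibroblasts, changed by 1.49 ± 0.12, from 0.0497 ± 0.0163 to 1.05 ± 0.0549 RPKM. Other abundant fibroblast transcripts stayed low in positive WM852 cells, at 0.0680 RPKM for COL1A2, 0.0421 RPKM for COL3A1 and 0.158 RPKM for DCN, against 3.14 RPKM for COL1A1. CD68, a macrophage marker, rose by 0.30 in WM852 and by 0.28 in WM115, and LYZ, the only other blood cell marker that could be tested, did not pass in either line.

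NF-kB targets, actin cytoskeleton genes and YAP and TEAD targets passed as lists in WM852 with the preset correlation only. Of 17 NF-kB targets, 6 rose and 11 did not pass, and 6 rose when adjusted over the list alone. CCL2 and CXCL8, chemokines that attract monocytes and neutrophils, rose by 2.15 ± 0.12 and 1.41 ± 0.15, and NFKBIA, the NF-kB inhibitor, by 0.26 ± 0.04. The list median was -0.01 while its mean was 0.26 and its test was upward (adjusted p = 0.0198, and adjusted p = 0.13 with an estimated correlation). Of 38 genes of the actin cytoskeleton, 7 rose, 2 fell and 29 did not pass, and 9 rose and 2 fell when adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.23 with an estimated correlation). Their median was 0.01 and their mean 0.12. MYL9, a myosin light chain, rose by 1.77 ± 0.14, TAGLN, an actin-binding protein of smooth muscle, by 1.19 ± 0.11, and VCL, vinculin of focal adhesions, by 0.50 ± 0.03. With each WM852 library left out in turn, 1 or 2 actin genes and 0 or 1 YAP target fell. Without positive library 2 or negative library 3 the actin list missed the threshold, at adjusted p = 0.0794 and 0.0544, and its adjusted p over all alternatives ran from 1.7e-05 to 0.23. Of 20 YAP and TEAD targets, 6 rose, 1 fell and 13 did not pass, and 9 rose and 1 fell when adjusted over the list alone. The matricellular genes CYR61 and CTGF rose by 0.57 ± 0.04 and 0.38 ± 0.05 (adjusted p = 8.6e-05 for the list, and adjusted p = 0.087 with an estimated correlation).

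S phase genes fell as a list in WM852, by small amounts. Of 25 S phase genes, 3 fell and 22 did not pass, and 9 fell when adjusted over the list alone, with a median log2 fold change of -0.08 (adjusted p = 7.4e-08, and 0.0169 with an estimated correlation). With each of the 6 WM852 libraries left out in turn, 0 or 1 member fell. Cytosolic ribosomal proteins had a median of -0.07 over 74 genes, of which 1 fell and 73 did not pass (adjusted p = 6.2e-10, and adjusted p = 0.23 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.04, with 1 member higher, 2 lower and 22 not past the test, and 1 higher and 7 lower when adjusted over the list alone (adjusted p = 0.000348, and adjusted p = 0.23 with an estimated correlation). No member of the autophagy and lysosome list or of the heat shock list passed by itself, over all genes or when adjusted over the list alone. Autophagy and lysosome genes had a median of 0.04 (adjusted p = 0.0198, and adjusted p = 0.0703 with an estimated correlation) and heat shock genes a median of -0.04 (adjusted p = 0.0371, and adjusted p = 0.107 with an estimated correlation). The heat shock call was also lost with quantile normalization, at adjusted p = 0.435, and without positive library 3 or negative library 2, at 0.144 and 0.0943, the range over its alternatives being 0.0102 to 0.435. With each WM852 library left out in turn, 0 to 5 ribosomal proteins, 0 to 2 hypoxia genes and 0 or 1 heat shock gene fell. In total 14 of 30 testable lists passed in WM852, 10 upward and 4 downward, and 7 of them held with an estimated correlation.

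In WM115 fewer genes changed at least 2-fold between reporter states than in WM852. UCA1, a long non-coding RNA, rose from 2.36 ± 0.310 to 6.75 ± 0.254 RPKM (SD, n = 3), a log2 fold change of 1.35 ± 0.13 (adjusted p = 0.00027). ITGB4, the integrin beta 4 subunit, rose by 0.84 ± 0.08 (adjusted p = 0.00027), C3, the central complement component, by 0.83 ± 0.06 (adjusted p = 3.9e-05), and MMP1 by 0.74 ± 0.05. APOBEC3G, a cytidine deaminase that restricts retroviruses, rose by 0.76 ± 0.05, PTHLH, a parathyroid hormone-like factor, by 0.67 ± 0.05, and FERMT1, the integrin activator kindlin-1, by 0.63 ± 0.03. SERPINA3 (Entrez gene 12, chromosome 14, 94612391 to 94624053) fell from 15.9 ± 1.42 to 5.54 ± 0.824 RPKM, a log2 fold change of -1.45 ± 0.10 (adjusted p = 3.1e-05). SOD3 changed by -1.19 ± 0.10, S100A1 by -0.72 ± 0.11, CHRDL1, a secreted BMP antagonist, by -0.70 ± 0.06, TXNIP by -0.61 ± 0.08, and AIM2, a sensor of cytosolic DNA, by -0.57 ± 0.08. ITGA9, RXRG, a retinoid X receptor, and the collagenase MMP8 changed by -0.55 ± 0.07, -0.53 ± 0.10 and -0.47 ± 0.09.

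Small RNAs were also among the largest changes in WM115, on few reads. SNORD59B, MIR3605 and SNORD34 changed by 1.45 ± 0.34, 1.36 ± 0.33 and 0.65 ± 0.16, and MIR589 by -1.19 ± 0.25. SNORD59B had 14 reads over the 3 positive libraries and 4 over the negative ones, and MIR589 had 8 and 22. One value per gene does not separate reads of a small RNA from reads of a longer transcript that spans it. In all, 466 genes passed in WM115, 220 higher and 246 lower in positive cells, and 9 of them changed at least 2-fold, 4 higher and 5 lower. Which direction held more genes depended on the processing. More were higher with median-ratio scaling (265 against 216 lower), quantile normalization (232 against 201), limma voom (367 against 279) and only the WM115 libraries fitted (59 against 45), and without positive library 1 (148 against 116), negative library 1 (168 against 165) or negative library 3 (122 against 93). The count was 264 without positive library 1, 245 without positive library 2, 215 without negative library 3, and 104 when only the WM115 libraries were fitted. By contrast, fitting only the WM852 libraries gave 509 genes for WM852, against 550. Leaving out the 6 WM115 libraries singly ended the call without 6 of them for SNORD59B, SNORD34 and MIR589, 5 for MIR3605, 3 for MMP8 and, for RXRG, without negative library 3, and over all alternatives adjusted p went up to 0.191 for SNORD59B, 0.245 for SNORD34, 0.139 for MIR589, 0.142 for MIR3605, 0.0699 for MMP8 and 0.059 for RXRG.

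As lists, S phase genes and G2 and M phase genes fell and p53 target genes rose in reporter-positive WM115 cells. Of 25 S phase genes, 9 fell and 16 did not pass, and 22 fell when adjusted over the list alone, with a median log2 fold change of -0.12 (adjusted p = 1.3e-15, and 0.00400 with an estimated correlation). The replicative helicase subunit MCM3 changed by -0.18 ± 0.02 and RRM2, a subunit of ribonucleotide reductase, by -0.18 ± 0.03. Of 25 G2 and M phase genes, 3 fell and 22 did not pass, and 18 fell when adjusted over the list alone, with a median of -0.10 (adjusted p = 1.8e-10, and 0.0377 with an estimated correlation). Cyclin A2, encoded by CCNA2, changed by -0.16 ± 0.03, and its call was lost when only the WM115 libraries were fitted (adjusted p = 0.0999, the highest over its alternatives, which began at 0.00659). Of 22 p53 targets, 5 rose and 17 did not pass, and 7 rose when adjusted over the list alone, with a median of 0.08 (adjusted p = 3.9e-08, and 0.00400 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose by 0.19 ± 0.03, the death receptor FAS by 0.26 ± 0.05 and the secreted stress factor GDF15 by 0.55 ± 0.13. These 3 calls were lost when only the WM115 libraries were fitted, at the highest adjusted p over their alternatives, 0.103, 0.131 and 0.145, and those of FAS and GDF15 also without 4 and 5 of the 6 WM115 libraries left out singly. With each of these libraries left out in turn, 5 to 13 S phase genes and 1 to 7 G2 and M phase genes fell, and 1 to 4 p53 targets rose.

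Other lists passed in WM115 with the preset correlation only. Of 5 epithelial markers, the keratins KRT18 and KRT8 rose by 0.25 ± 0.03 and 0.47 ± 0.07 and 3 did not pass, and 3 rose when adjusted over the list alone (adjusted p = 0.00070, and adjusted p = 0.0581 with an estimated correlation). Both keratins passed in WM852 too, at 0.17 ± 0.03 and 0.27 ± 0.07, without a call for the list (adjusted p = 0.273, median -0.01, mean 0.06), and there the KRT18 call was lost without positive library 2 or negative library 1 (adjusted p = 0.0608 and 0.0542) and the KRT8 call without 5 of the 6 libraries left out singly (adjusted p up to 0.162). DNA repair genes had a median of -0.07, with 2 of 26 lower and 24 not past the test, and 4 lower when adjusted over the list alone (adjusted p = 0.00328, and adjusted p = 0.364 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.05, with 1 higher, 2 lower and 22 not past the test, and 1 higher and 6 lower when adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.331 with an estimated correlation). Of 8 melanocyte differentiation genes tested, EDNRB fell and 7 did not pass, and 3 fell when adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.174 with an estimated correlation). Of 14 interferon-stimulated genes none passed by itself over all genes, and 3 rose when adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.19 with an estimated correlation). Of 21 TGF-beta targets 1 rose and 20 did not pass, and 3 rose when adjusted over the list alone (adjusted p = 0.0364, and adjusted p = 0.308 with an estimated correlation). Of 4 fibroblast markers the proteoglycan gene LUM rose by 0.47 ± 0.05 and 3 did not pass, and 1 rose when adjusted over the list alone (adjusted p = 0.0372, and adjusted p = 0.174 with an estimated correlation). In total 10 of 30 lists passed, 5 upward and 5 downward, and 3 of them held with an estimated correlation. The DNA repair call was lost without negative library 1 (adjusted p = 0.0811, over all alternatives 1.4e-05 to 0.364) and the hypoxia call without positive library 3 or negative library 2 (0.0533 and 0.102, over all alternatives 7.7e-05 to 0.331). With the 6 WM115 libraries left out singly, the call was lost without 2 of them for melanocyte genes (positive library 3 and negative library 2), 3 for interferon-stimulated genes, 3 for TGF-beta targets and 5 for fibroblast markers, and over all alternatives adjusted p went up to 0.473, 0.19, 0.308 and 0.326. Members past the threshold then ran from 1 to 4 lower for DNA repair, 0 to 3 lower and 0 or 1 higher for hypoxia, 1 or 2 lower for melanocyte genes, and 0 or 1 and 0 to 2 higher for interferon-stimulated genes and TGF-beta targets.

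The AP-1, JNK feedback and motility lists were written knowing the topic of the study. As lists, AP-1 subunits and MAPK and JNK feedback regulators did not pass in either line. Of 13 AP-1 subunits, JUN and FOSL2 rose in WM852, by 0.33 ± 0.05 and 0.26 ± 0.05, and 11 did not pass, with 2 higher when adjusted over the list alone (list adjusted p = 0.788, median -0.01, mean 0.00, upward test). The FOSL2 call was lost without positive library 1, positive library 2 or negative library 3, at adjusted p = 0.0544, 0.0717 and 0.0589, and over all alternatives its adjusted p began at 0.00028. In WM115 none of the 13 passed (list adjusted p = 0.411). Of 19 feedback regulators, the phosphatase DUSP1 rose by 0.24 ± 0.05 in WM852, SPRY2 fell by 0.13 ± 0.03 and 17 did not pass, with 2 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.859, median 0.01, mean 0.01, downward test). The SPRY2 call was lost with quantile normalization, at adjusted p = 0.0742, the highest over its alternatives, which began at 0.00529, and without positive library 2 or negative library 2, at 0.0656 and 0.0504. In WM115, SPRY4, another inhibitor of this pathway, fell by 0.29 ± 0.03 and 18 did not pass, with 2 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.528).

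Caspases and BCL2 family genes did not pass as lists in either line. No caspase or caspase regulator among 15 passed in either line, over all genes or when adjusted over the list alone (list adjusted p = 0.673 in WM852 and 0.528 in WM115). Of 13 BCL2 family genes, BOK, a pore-forming member, was among 3 that rose in WM852, at 0.50 ± 0.07, and 10 did not pass, with 3 higher when adjusted over the list alone (list adjusted p = 0.317). With each of the 6 WM852 libraries left out in turn, 1 or 2 of them rose. In WM115 no BCL2 family gene passed over all genes and 1 was higher when adjusted over the list alone (list adjusted p = 0.323). Genes of the ATF4 response (adjusted p = 0.859 and 0.528 in WM852 and WM115), endoplasmic reticulum chaperones (0.247 and 0.827), other immediate early genes (0.206 and 0.426), oxidative phosphorylation (0.273 and 0.628), cholesterol synthesis (0.124 and 0.224) and replication-dependent histones (0.857 and 0.268) did not pass as lists in either line. In WM852, p53 targets (0.0545), TGF-beta targets (0.056), DNA repair (0.312), G2 and M phase genes (0.476) and melanocyte differentiation genes (0.442) did not pass, and in WM115 autophagy (0.125), undifferentiated-state genes (0.125), proteases (0.125), heat shock (0.224), mesenchymal genes (0.268), ribosomal proteins (0.606), NF-kB targets (0.671), integrins (0.818), actin genes (0.826) and YAP targets (0.891) did not. Of 25 proteases in WM115, 6 rose, 4 fell and 15 did not pass, with 7 higher and 5 lower when adjusted over the list alone, and 2 to 5 rose and 0 to 3 fell with each WM115 library left out in turn. Of 16 undifferentiated-state genes there, 4 rose, 2 fell and 10 did not pass, and with a library left out 2 or 3 rose and 1 fell. In other lists, 2 mesenchymal genes fell, and 1 integrin rose and 2 fell. Actin genes and YAP targets each had 1 higher and 2 lower. Leaving out 1 WM115 library gave 0 to 2 lower for mesenchymal, actin and YAP genes. Among the rest, 1 NF-kB target fell and 1 autophagy gene rose. In WM852, 5 of 21 TGF-beta targets rose, 1 fell and 15 did not pass, with a median of 0.04 against 0.03 in WM115. With each WM852 library left out in turn, 2 to 4 of them rose and 0 fell. The effect on this list did not differ between the lines (camera adjusted p = 0.734). Of 8 melanocyte genes in WM852, 1 rose, 2 fell and 5 did not pass, and with a library left out 0 or 1 rose and 1 or 2 fell.

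**Figure D1:**
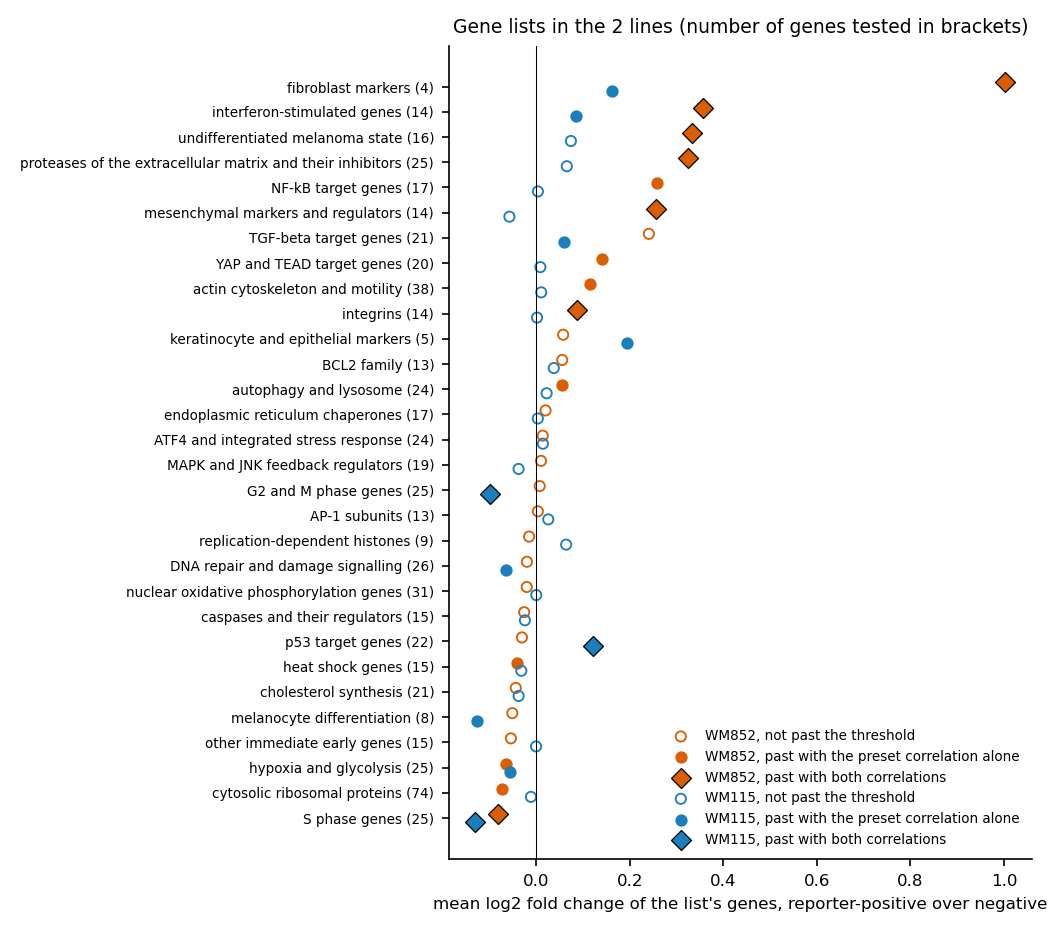
Mean log2 fold change (log2(RPKM + 0.5) scale) of each gene list between reporter-positive and reporter-negative cells in WM852 and in WM115, with filled symbols for lists past the camera test at the preset correlation and diamonds for those that also passed with an estimated correlation. Of 30 lists, 14 passed in WM852 and 10 in WM115, and 7 and 3 of these held with an estimated correlation.

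Both lines shared a set of genes that moved in the same direction with the reporter. C3 (Entrez gene 718, chromosome 19, 6677704 to 6720650) rose by 1.42 ± 0.06 in WM852 and by 0.83 ± 0.06 in WM115, and SPP1, the secreted phosphoprotein osteopontin, by 1.17 ± 0.07 and 0.55 ± 0.07. ITGB4 rose by 0.45 ± 0.08 and 0.84 ± 0.08 and MISP, an actin-bundling protein, by 0.47 ± 0.08 and 0.44 ± 0.08. TM4SF18 rose by 0.65 ± 0.07 and 0.56 ± 0.07, ANKRD1, a YAP target, by 0.49 ± 0.07 and 0.54 ± 0.07, MVP, the major vault protein, by 0.40 ± 0.05 and 0.39 ± 0.05, and MMP1 by 0.38 ± 0.05 and 0.74 ± 0.05. The log2 fold changes of APOBEC3G were 0.40 ± 0.05 and 0.76 ± 0.05, and those of the hair keratin KRT81 were 0.42 ± 0.09 and 0.48 ± 0.09. SOD3, SERPINA3, TXNIP, S100A1 and CHRDL1 fell in both lines by the amounts given above. EDNRB changed by -0.62 ± 0.07 and -0.46 ± 0.07, TFAP2B, a transcription factor of the neural crest, by -0.41 ± 0.05 and -0.43 ± 0.05, SLAIN1 by -0.45 ± 0.07 and -0.42 ± 0.07, HMCN1, a matrix protein, by -0.45 ± 0.06 and -0.39 ± 0.06, and ITGA9 by -0.39 ± 0.07 and -0.55 ± 0.07.

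**Figure D2:**
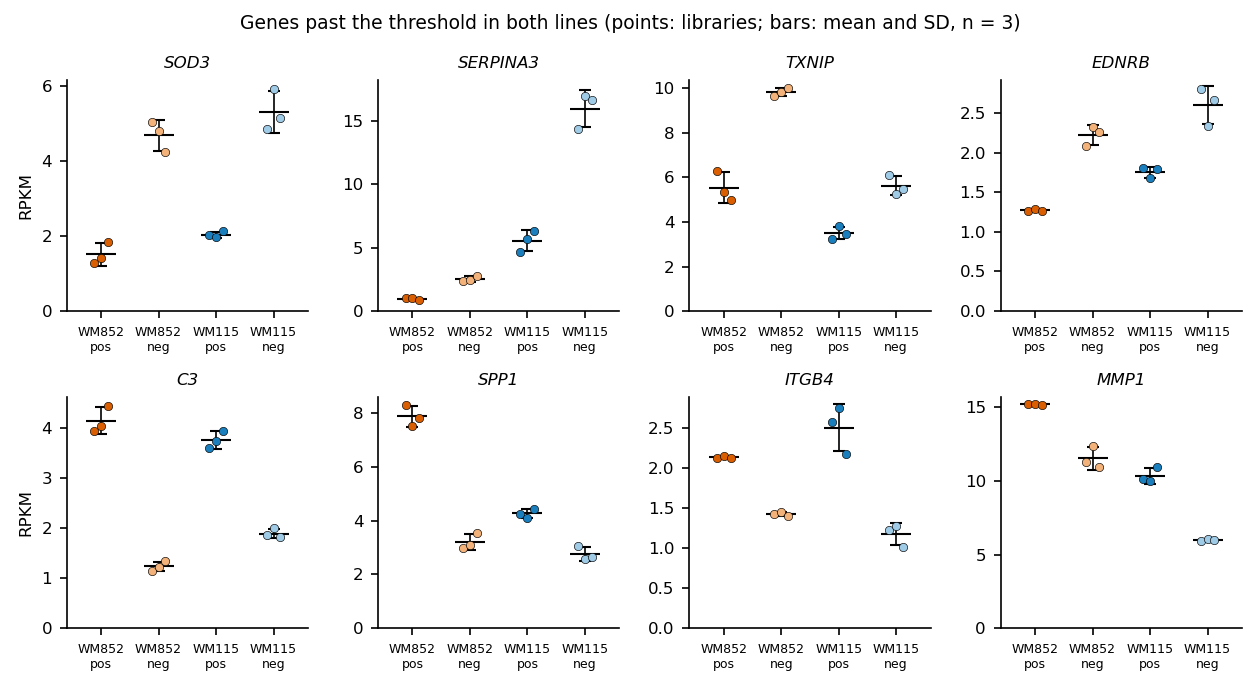
RPKM of 8 genes that passed in both lines, per library (points), with the mean and standard deviation of the 3 libraries of each group. C3, SPP1, ITGB4 and MMP1 were higher and SOD3, SERPINA3, TXNIP and EDNRB lower in positive cells of both lines.

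In total 88 genes rose in both lines, against 6.95 for independent lists of these lengths (Fisher's exact test, two-sided, p = 1.3e-75), and 59 fell in both, against 3.16 (p = 1.2e-60). Genes are not independent replicates, so these p-values describe the overlap of the lists. The comparisons share no library, but both took the spread of each gene from the same model of 12 libraries. A gene of small spread could therefore pass more easily in both, and the numbers for independent lists do not allow for this. Of 156 genes past the threshold in both lines, 147 moved in the same direction and 9 in opposite directions. Across genes, the fold changes of both lines had a Pearson r of 0.172 and a Spearman rho of 0.257 over all 12376 genes, and an r of 0.771 over the genes that passed in both. The choice of genes by their calls leaves out values near 0 and so raises the last r. The count of 147 was 93, 89, 96, 90 and 90 without WM852 positive library 1, 2 or 3 or negative library 1 or 3, and 86 without WM115 negative library 3, 51 when only the libraries of each line were fitted, and 256 with limma voom on the recovered reads. The KRT81 calls in both lines, the S100A1 call in WM852 and the EDNRB, SLAIN1 and HMCN1 calls in WM115 were lost in some alternatives, with adjusted p up to 0.0966 (WM852) and 0.087 (WM115) for KRT81, 0.0705 for S100A1, 0.0508 for EDNRB, 0.0585 for SLAIN1 and 0.0625 for HMCN1. Of these, KRT81 lost its call without 4 of the 6 WM852 and 3 of the 6 WM115 libraries left out singly, and SLAIN1 without WM115 negative library 3 (adjusted p = 0.0502).

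**Figure D3:**
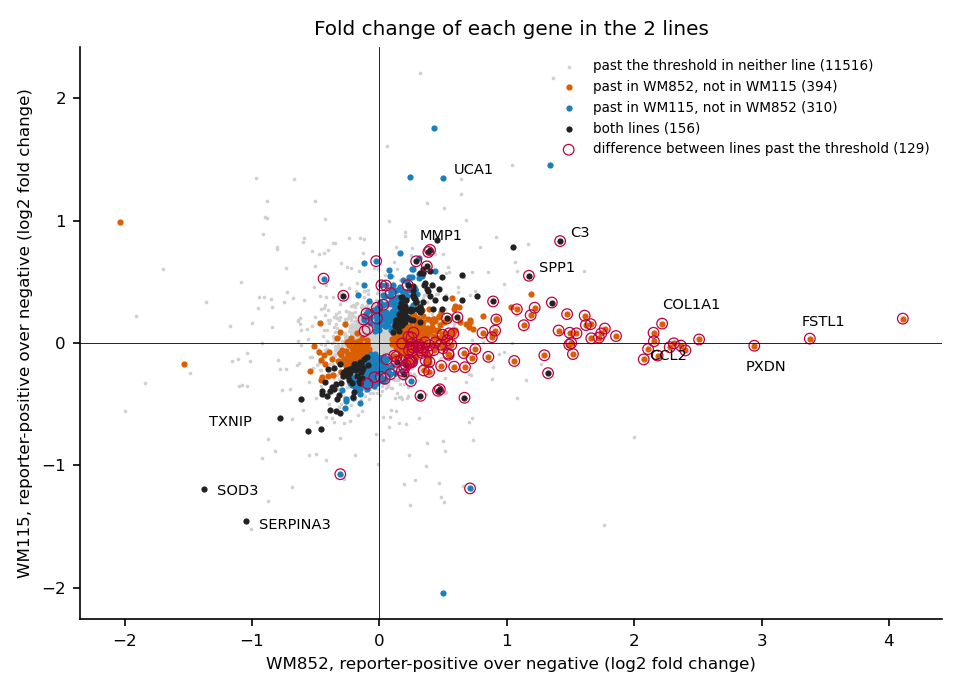
Log2 fold change (log2(RPKM + 0.5) scale) between reporter-positive and reporter-negative cells for each of 12376 genes, WM852 on the horizontal axis and WM115 on the vertical axis, coloured by the line in which a gene passed and marked where the difference between lines passed. FSTL1, PXDN and COL1A1 lie far to the right and near 0 on the WM115 axis.

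The difference between positive and negative cells, here called the effect of the reporter state, varied between lines, mainly through genes that rose in WM852. Cells were sorted into these states and not assigned to them, so the term names no cause. The difference of the log2 fold changes (WM852 minus WM115) was 3.34 ± 0.12 for FSTL1 (adjusted p = 4.9e-08), 2.97 ± 0.13 for PXDN, 2.48 ± 0.14 for FLNC and 2.46 ± 0.17 for CNN1. In WM115, FSTL1 was at 1.08 ± 0.0333 RPKM in positive and 1.05 ± 0.138 RPKM in negative cells, and PXDN at 0.00551 and 0.0132 RPKM. CCL2, COL1A1, MYL9, PLAU, SOX9, CXCL8 and F2RL1 also rose more in WM852, with differences of 2.07 ± 0.17, 2.06 ± 0.12, 1.65 ± 0.20, 1.62 ± 0.17, 1.39 ± 0.16, 1.30 ± 0.21 and 1.02 ± 0.10. The lowest differences were those of IGFBP5, an insulin-like growth factor binding protein, at -0.67 ± 0.08 (adjusted p = 0.00090), LUM at -0.46 ± 0.08, KIAA0040 at -0.42 ± 0.07, PTHLH at -0.38 ± 0.07 and APOBEC3G at -0.36 ± 0.08. IGFBP5 changed by -0.28 ± 0.05 in WM852 and by 0.39 ± 0.05 in WM115. In all, 129 genes differed in their effect, 111 with the higher effect in WM852 and 18 with the lower, and 85 of them passed in WM852 and not in WM115. Genes with the lower effect ran from 11 (without WM115 positive library 2) to 34 (without WM115 negative library 2) with 1 library left out, and were 62 with limma voom.

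**Figure D4:**
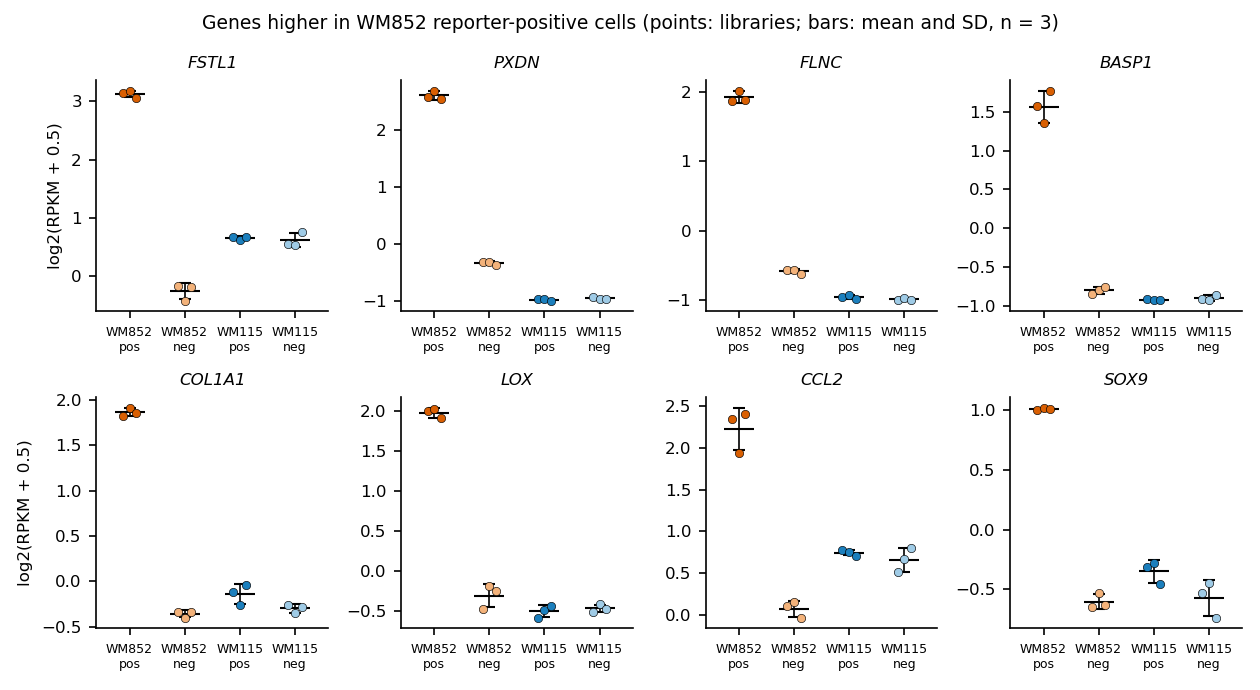
Log2(RPKM + 0.5) per library (points) with the group mean and standard deviation for 8 genes whose effect differed between lines, in reporter-positive and reporter-negative cells of WM852 and WM115 (3 libraries per group). FSTL1, PXDN, FLNC, BASP1, COL1A1, LOX, CCL2 and SOX9 are higher in the positive WM852 libraries than in the negative ones.

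The effect of the reporter state also differed between lines for 14 gene lists, 11 with the higher effect in WM852 and 3 with the lower. A higher effect means a more positive log2 fold change, not a larger change. For p53 targets the positive-negative effect was lower in WM852 than in WM115, with a median difference of -0.14, 1 of 22 members lower and 21 not past the test, and 5 lower when adjusted over the list alone (adjusted p = 7.0e-10, and 0.00238 with an estimated correlation). CDKN1A was that member, at -0.32 ± 0.05. The negative libraries enter this difference with the opposite sign to the comparison of negative cells between lines, so those results are not independent. For G2 and M phase genes the effect was higher in WM852, with a median difference of 0.11 and 8 members higher when adjusted over the list alone (adjusted p = 1.3e-08, and 0.0491 with an estimated correlation), though none of the 25 passed over all genes. As a list they fell in WM115 (median -0.10) and did not pass in WM852 (median 0.014). The difference thus reflected the decrease in WM115 rather than an increase in WM852. Of 16 undifferentiated-state genes, 3 had a higher effect in WM852 and 13 did not pass, and 8 were higher and 2 lower when adjusted over the list alone (adjusted p = 3.6e-07, and 0.042 with an estimated correlation). Of 14 mesenchymal genes, 4 had a higher effect and 10 did not pass, and 6 had a higher one when adjusted over the list alone (adjusted p = 3.5e-06, and 0.0262 with an estimated correlation). With each of the 12 libraries left out in turn, 1 to 5 mesenchymal, 2 to 4 undifferentiated-state and 0 to 2 G2 and M phase genes had a higher effect in WM852. A further 10 lists passed with the preset correlation and not with the estimated one. The count of 129 was 240 with no filter on low values, 43 when only genes with a mean of at least 5 RPKM were tested, and 226 with limma voom on the recovered reads. The calls of FLNC, PTHLH and APOBEC3G were lost in some alternatives, with adjusted p up to 0.0743 for FLNC (limma voom), 0.0763 for PTHLH and 0.129 for APOBEC3G, the last 2 without 8 and 11 of the 12 libraries left out singly.

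Reporter-negative cells of WM852 and WM115 were compared to describe the lines themselves, and they differed in many genes by small amounts. PDE2A, a cyclic nucleotide phosphodiesterase (Entrez gene 5138, chromosome 11, 72576141 to 72674422), was at 2.71 ± 0.137 RPKM in WM852 and 0.351 ± 0.0770 RPKM in WM115, a log2 difference of 1.92 ± 0.08 (adjusted p = 2.0e-08). XYLT1, a xylosyltransferase of proteoglycan synthesis, ARHGAP28, a GTPase-activating protein, and ANGPTL2, a secreted angiopoietin-like protein, were higher in WM852 by 1.79 ± 0.08, 1.69 ± 0.07 and 1.65 ± 0.04. FAM133A, the transcription factor PAX8, C16orf54, the ephrin receptor EPHA7 and the cyclin CCNA1 were higher by 1.71 ± 0.08, 1.63 ± 0.09, 1.61 ± 0.09, 1.33 ± 0.07 and 1.27 ± 0.06. SERPINA3 and SDC2, a cell-surface heparan sulfate proteoglycan, were lower in WM852, at -2.45 ± 0.10 and -2.22 ± 0.07, as were TMEM98 (-1.57 ± 0.09), UCA1 (-1.56 ± 0.13), the prostaglandin E synthase PTGES (-1.31 ± 0.09), lipoprotein lipase LPL (-1.30 ± 0.08), EEF1AKMT1 (-1.28 ± 0.09) and the ephrin receptor EPHB2 (-1.22 ± 0.08). GAGE2B and GAGE12B, at -1.60 ± 0.22 and -1.24 ± 0.15, belong to a family of near-identical copies whose reads the counting could have split, and TRK-TTT2-1, a transfer RNA gene at 1.42 ± 0.36, rested on 9 against 2 reads. In total 3337 genes passed, 1823 higher and 1514 lower in WM852, with a median absolute log2 difference of 0.25, and 80 of them differed at least 2-fold. The excess of higher genes turned with quantile normalization (1632 higher, 1717 lower) and with limma voom (1874 higher, 1893 lower). Across genes, the mean log2 levels of the negative groups had a Pearson r of 0.992, and no gene was at 5 RPKM or more in one line and under 0.2 RPKM in the other. Between positive and negative cells this r was 0.995 in WM852 and 0.997 in WM115. One cell line, or a mixture, behind both names was not excluded, a limit that also holds for the genes shared by the lines. The TRK-TTT2-1 call was lost with limma voom, at adjusted p = 0.0575, the highest over its alternatives, which began at 0.00991, and without WM852 negative library 2, at 0.0536.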

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

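The tests of the source of the genes seen in WM852 and of the likeness of the lines were chosen only after the results were seen, whereas the counts over other splits of the libraries were fixed beforehand. Results appear here because the effect of the reporter state differed between the lines by a test of the difference itself (limma, WM852 minus WM115). This held for 129 genes. Among the genes named in the text it held for 41, with the effect higher in WM852 for 32 and lower for 9.

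Differences on the log2 scale were 3.34 for FSTL1, 2.97 for PXDN, 2.48 for FLNC, 2.46 for CNN1, 2.39 for BASP1, 2.31 for UCHL1, 2.31 for LOX and 2.29 for RAC2. They were 2.07 for CCL2, 2.06 for COL1A1, 1.90 for MIR589 (on few reads), 1.65 for MYL9, 1.62 for PLAU, 1.504 for FAP, 1.40 for BST2, 1.39 for SOX9, 1.30 for CXCL8 and 1.02 for F2RL1. Smaller values were those of TAGLN (0.96), SNAI2 (0.87), DDX58 (0.83), SDC2 (0.75), SPP1 (0.62), C3 (0.59), CYR61 (0.58), CTGF (0.45), VCL (0.43), JUN (0.39), TIMP2 (0.38), ITGA4 (0.33), NFKBIA (0.32) and FN1 (0.18). The effect was lower in WM852 for MMP2 (-0.25), FERMT1 (-0.25), CDKN1A (-0.32), MMP1 (-0.36), APOBEC3G (-0.36), PTHLH (-0.38), KIAA0040 (-0.42), LUM (-0.46) and IGFBP5 (-0.67). Among these, the calls of FLNC, FAP, SNAI2, JUN, NFKBIA, FN1, PTHLH, APOBEC3G, MIR589, MMP1 and FERMT1 were lost in some alternatives, with adjusted p up to 0.0743, 0.0907, 0.116, 0.0551, 0.0727, 0.122, 0.0763, 0.129, 0.0934, 0.0674 and 0.0557.

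Of the gene lists, 14 differed in their effect between the lines. The median difference was -0.14 for p53 targets, 0.11 for G2 and M phase genes, 0.22 for undifferentiated-state genes and 0.13 for mesenchymal genes, which held with an estimated correlation. It was -0.059 for ribosomal proteins, 0.082 for YAP targets, 0.88 for fibroblast markers, 0.10 for integrins, 0.067 for proteases, 0.056 for S phase genes, 0.14 for interferon-stimulated genes, -0.17 for epithelial markers, 0.17 for NF-kB targets and 0.012 for actin genes. S phase genes fell in both lines, by less in WM852 (median -0.08 against -0.12). The interferon-stimulated median turned to -0.043 (adjusted p = 0.986) when only genes with a mean of at least 5 RPKM were tested, and the list also missed the threshold without WM115 negative library 2 (adjusted p = 0.0575, over all alternatives 8.8e-05 to 0.986). The NF-kB call was lost with a mean of at least 5 RPKM and without WM115 negative library 2 or positive library 3 (adjusted p = 0.119, 0.0557 and 0.0704, over all alternatives 0.00030 to 0.146). The epithelial call was lost with no filter (0.0958, over all alternatives 0.0054 to 0.104), and the actin call without WM852 positive library 2, WM852 negative library 3 or WM115 positive library 3 (0.0879, 0.0611 and 0.202, over all alternatives 0.0015 to 0.262). The last 10 lists missed the threshold with an estimated correlation, at adjusted p = 0.376, 0.104, 0.0522, 0.0522, 0.0918, 0.147, 0.104, 0.104, 0.146 and 0.262, respectively.

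Genes near 0 in the WM115 libraries and far higher in positive than in negative WM852 cells formed the first pattern: in 7 of them (PXDN, FLNC, CNN1, BASP1, UCHL1, FAP and, chosen after its values were seen, TNFRSF10D) the negative libraries held between 0.0301 and 0.0673 of the positive level, 5.21% when pooled. Among COL1A2, COL3A1 and DCN the highest level in positive WM852 cells was 0.158 RPKM (DCN), beside 3.14 RPKM of COL1A1. This argues only against fibroblasts that express those genes at levels near COL1A1. The genes were chosen after values were seen, and the fibroblast markers COL1A1 and FAP rose. Fibroblast-like cells of another profile were therefore not excluded. Reads passed to all other libraries alike are argued against by 13 genes chosen by their WM852 levels alone. They had at least 1 RPKM in positive cells, at most 10% of it in negative cells and at least 100 reads. Of these, 8 had fewer reads in the higher WM115 group than the share in negative WM852 cells predicts (exact test). PXDN had 5 against 123. The ratio differed between the 7 genes, chosen with no condition on negative WM852 cells, by a chi-square of 0.865 per degree of freedom, below the 1.31 to 2.32 between replicate WM852 libraries, so one source of these transcripts with a smaller share in the negative libraries is a candidate explanation for these genes, though 4 of them had under 30 reads in negative WM852 cells, which can hide a difference, and with a wider limit on the WM115 level 13 genes gave 75.0 per degree of freedom, with AGTR1 at a ratio of 0.937. Reads passed between the WM852 libraries alone, which held a median of 5.34% of the positive level in negative cells for the 13 genes chosen by WM852 levels, cannot be told apart from such a source, because the labels name no runs. Whether that source would be a minor population of cells, positive cells sorted as negative, or a gene programme switched on along with caspases stays open, the last as an untested biological explanation.

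Few large differences between the lines formed the second pattern. Of 12376 genes, 103 differed at least 2-fold between negative WM852 and negative WM115 cells, whether or not they passed the test. By the same count, 76 differed between positive and negative cells of WM852 and 40 between those of WM115. Adjustment or smoothing of values between libraries after counting is argued against by the whole reads recovered for 100% of kept genes. Changes made before counting, or ones that return whole reads, would pass the same check and were not tested. One cell line, or a mixture, behind both names cannot be told apart from lines of like expression with these 103 genes, because no reference profile or genotype of the lines was used. A difference between the lines in metastatic potential, which the labels name, stays open as untested.

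Other splits of the libraries were counted for each result of the model. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In WM852 the real split gave 550 genes and the highest other 0 (1 split of 10 with as many genes), in WM115 466 and 1 (1 of 10), and between the lines 3337 and 0 (1 of 10). For the difference of effects, 3 of 100 splits drawn from 200 gave as many genes as the real 129, and the highest other split gave 238 genes. The splits with more genes than the real one kept the WM852 groups whole or exchanged them and mixed the WM115 libraries. This count therefore follows the WM852 effect more than a contrast of both lines, and it does not exclude chance for the difference. For genes past the threshold in both lines in the same direction, 1 of 100 splits gave as many as the real 147 and the highest other gave 1. Other splits within a line gave at most 1 gene, so the overlap under them was bound to be near 0 and this count does not exclude chance for the sharing.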

How the results depend on the processing

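Limma voom was chosen only after the data were seen. No call of a named gene changed direction under any alternative, and 1 of the 3337 line differences did with quantile normalization. Medians of called lists changed sign for interferon-stimulated genes in the difference of effects (0.14 to -0.043, mean of at least 5 RPKM), melanocyte genes in WM115 (-0.083 to 0.0054, no filter) and NF-kB targets in WM852 (-0.01 to between 0.0056 and 0.13 in 5 alternatives). The 2-fold minimum was not run for gene lists, since it applies to single genes. Of the main 550 (WM852), 466 (WM115), 129 (difference of effects), 3337 (lines) and 147 genes (both lines), a 2-fold minimum left 46, 9, 35, 80 and 2, which follows from the minimum itself. A mean of at least 5 RPKM gave 315 for WM852 and 43 for the difference, with fewer genes tested (7915), and no filter gave 240 for the difference. Fits of only the libraries compared gave 104 for WM115 and 51 for both lines, with fewer samples, but 509 for WM852 on as few samples. Fewer samples alone therefore do not account for the WM115 loss. Calls in WM115 depended more on the spread taken over all 12 libraries. Limma voom gave 903, 226 and 256 for WM852, the difference and both lines, and moved the share of higher calls in the difference from 86.0% to 72.6%. The cause was not tested for voom or for the fit with no filter. With 1 library left out the counts ran from 301 to 383 in WM852, from 215 to 485 in WM115 and from 86 to 145 in both lines, with fewer samples. Without WM115 negative library 2, whose reads lay farthest from its replicates, WM115 gave 485 genes. With an estimated correlation 7, 3 and 4 lists passed (WM852, WM115, difference) in place of 14, 10 and 14. Apart from the replicate block below, every other total of genes or of lists past the threshold stayed within 1.5 times its main value. Counts of a single direction moved by more in places. Lower genes in WM852 fell from 159 to 65 without positive library 2, and lower effects in the difference went from 18 to 62 with limma voom. Of the genes that the naming rule took for each comparison (and, for differences, all genes named in the text) and that passed, 79 of 98 in WM852, 31 of 72 in WM115, 36 of 45 differences and 122 of 129 line differences passed in every alternative that used all replicates, and 65, 41, 33 and 123 whichever library was left out. Several small RNAs named in the text rested on few reads, and how far depth limits the calls at each level was not tested.

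Replicate numbers showed no clear pairing of the libraries, though 3 libraries per group cannot exclude it. Positive and negative libraries of the same number had correlations of their deviations between -0.0460 and 0.0162 in WM852 and between 0.0254 and 0.0925 in WM115, and only WM115 libraries 2 and 3 deviated most like their own number. With the number as a block, the counts were 355 in WM852, 244 in WM115, 79 for the difference and 87 in both lines. Of 344 calls of these genes and 46 of lists, 55 and 2 (TGF-beta targets and fibroblast markers in WM115) missed the threshold, and ranges over alternatives in the text leave the block out.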

Other observations

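All comparisons here were fixed before the data were examined. The comparison of negative cells and the difference of effects use the same negative libraries with opposite sign. Opposite results in them, as for p53 targets and G2 and M phase genes, are therefore not independent. Reporter-negative cells of the lines differed in several gene lists not described so far. Mitotic genes were lower in WM852 than in WM115. Of 25 G2 and M phase genes, 21 were lower, 1 higher and 3 not past the test, and 22 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.1e-10, and 0.0394 with an estimated correlation). The mitotic kinase gene AURKA differed by -0.39 ± 0.03 on the log2 scale and the proliferation marker MKI67 by -0.22 ± 0.03, whereas S phase genes did not pass as a list (adjusted p = 0.873, median -0.02, mean 0.00). Matrix proteases were higher in WM852, with 15 of 25 higher, 3 lower and 7 not past the test, and 15 higher and 4 lower when adjusted over the list alone (adjusted p = 0.000317, and 0.0405 with an estimated correlation). MMP1 differed by 0.89 ± 0.05 and MMP2 by 0.72 ± 0.03.

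Feedback regulators of MAPK and JNK were higher in WM852, with 11 of 19 higher, 2 lower and 6 not past the test, and 11 higher and 3 lower when adjusted over the list alone (adjusted p = 0.00548, and 0.0405 with an estimated correlation). SPRY2 and SPRY4, inhibitors of receptor signalling, differed by 0.38 ± 0.03 and 0.37 ± 0.03. Of 22 p53 targets, 6 were higher and 16 not past the test, with 6 higher when adjusted over the list alone (adjusted p = 0.00548, and 0.0405 with an estimated correlation), among them CDKN1A at 0.34 ± 0.03. Of 15 heat shock genes, 8 were higher, 1 lower and 6 not past the test, with 10 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00029, and 0.0394 with an estimated correlation), and HSPA1A, whose near-identical copy HSPA1B can share its reads, differed by 0.60 ± 0.07. Replication-dependent histone genes were higher in 7 of 9 cases, with 2 not past the test and 7 higher when adjusted over the list alone (adjusted p = 0.000287, and 0.0394 with an estimated correlation). HIST1H2AC and HIST1H2BK differed by 1.25 ± 0.15 and 0.93 ± 0.05, and poly(A) selection recovers such transcripts poorly. Of 15 other immediate early genes, 6 were higher and 9 not past the test, with 6 higher when adjusted over the list alone (adjusted p = 0.00772, and adjusted p = 0.0932 with an estimated correlation). Ribosomal proteins had a median difference of -0.11, with 32 of 74 lower, 3 higher and 39 not past the test, and 45 lower and 3 higher when adjusted over the list alone (adjusted p = 2.2e-08, and adjusted p = 0.56 with an estimated correlation). With each negative library left out in turn, 14 to 35 ribosomal proteins were lower and 1 or 2 G2 and M phase genes higher. The other 22 lists did not pass.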
